A study of Schizosaccharomyces pombe with 13 samples.

How the data were processed

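The deposited data are libraries of Ago1-bound RNA of 18 to 30 nt from fission yeast, recovered by Flag purification from cells grown without leucine, with 1 library for each of 13 strains. Per the labels, the authors aligned the reads with Novoalign, whose version is not given in the sources used here, and the genome build is not stated. Positions were read on the reference sequence with chromosomes I, II and III of 5579133, 4539804 and 2452883 nt, from which the first base of wild type dg/dh reads differed in 0.508% of reads. Both aligned read files and peak files were deposited for each library. The aligned read files are of a kind with unit "other": per the file headers and values the authors list 1 line per read with its position, strand, mismatches, number of places in the genome, length and sequence, and no scaling. The peak files hold signal, which in the deposited files is read coverage per base scaled by the authors, with the strands pooled. All values of the comparisons came from the aligned reads, and the peak files were used only to check that each one matched its own library. Some of their columns carry a name other than the label, such as Rdp1_HU for wild type + ago1D580A, S11 for dis3-54,D171N and S13_ta for dcr1Δdis3-54,D171N, and each file still correlated most with the alignments of the library it was deposited with. In the dcr1Δ peak file 21.7% of values were not whole multiples of the smallest one, within 0.01 of it, so that more than 1 scale may be mixed, against 0 in the other files.

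Reads were counted by lines, with the 1 place that the authors list for reads with several. Each read was assigned by its middle base to 1 class, in this order of precedence: dg/dh outside tRNA genes, other centromeric sequence (imr and cnt), tlh genes, rRNA, tRNA, snRNA and snoRNA, Tf2 and LTR, protein-coding genes in sense, then in antisense, and other. The 6 outer repeat blocks of the 3 centromeres stand for dg/dh, since the annotation names neither dg nor dh, and they were bounded by the flanking tRNA genes and, at centromere 1, the IRC1 elements. The 50 nt downstream of a tRNA gene were counted with the tRNA. The 3′ ETS is the 100 nt downstream of each of 3 complete 28S rRNA genes, and flanks of centromere 3 are the 3000 nt on either side of its outer repeats. The numbers of annotated features were 171 tRNA genes, 36 5S rRNA genes, 13 Tf2 elements and 5113 protein-coding genes. Reads of deleted genes were counted over the coding span alone.

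The main values were the log2 ratio of the dg/dh share of aligned reads and the log2 ratio of the antisense share of reads of protein-coding genes, for 12 comparisons with wild type and 3 between mutant strains. Shares carry exact binomial (Clopper-Pearson) intervals, counts exact Poisson intervals, and log2 ratios an exact conditional interval, all at 95% and for counting error only. With 1 library per strain there was no test between strains and no p-values were given. Depth was between 1225697 and 6870265 aligned reads, so a count of 0, taken at a floor of 3 counts, allows a share of at most 0.000245% of aligned reads.

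For single genes, reads on each strand were scaled to RPM of the reads outside dg/dh, rRNA and tRNA, 5 RPM was added, and log2 ratios were taken. Genes with at least 50 reads on the strand in the higher library were counted as higher or lower past 4-fold. Where this scaling moved the sense median of all genes, the log2 ratios of named genes are given relative to that median. The total used for scaling includes reads in the flanks of centromere 3, which made 68.7% of it in wild type, so folds and gene counts without them are given as well. A gene with 0 reads in 1 library has a bound from the floor of 3 counts, and a gene with 1 to 3 reads has the ratio without a pseudocount and its counting interval. The genes named were the 10 with the largest higher and the 5 with the largest lower antisense ratios, and 5 each way in sense, for dis3-54,D171N, dcr1Δ and wild type + ago1D580A against wild type and for dcr1Δdis3-54,D171N against dcr1Δ. For the other comparisons they were the 3 largest each way in antisense, with the targeted genes, the heterochromatic loci and up to 4 members of a list.

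The 9 gene lists were RNAi and heterochromatin factors (16 genes), meiotic genes (10), glycolysis and translation (16), ribosomal proteins (141), histones (10), heat shock (9), thiamine and phosphate (7), Tf2 retrotransposons (13) and tlh genes (2), and 0 members were missing. Since nearly all reads of Tf2 spans have several places in the genome, Tf2 copies were also pooled, a choice made after the results were seen. Each list's median log2 ratio was placed among those of 10000 random lists of the same size drawn from 20 bins of level. Lengths, first bases, strands and last-base mismatches of dg/dh reads were tabulated. Distinct dg/dh reads of 20 to 24 nt were searched for an opposite-strand read leaving a 3′ overhang of 2 nt, and for overhangs of -6 to 6 nt.

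The comparisons, lists, naming rule and most alternatives were set before the data were examined. These alternatives were reads of 20 to 24 nt or 21 to 23 nt only, distinct sequences, perfect matches, single-place reads, a total without rRNA and tRNA, whole centromeres, a minimum of 20 reads or none, pseudocounts of 1 and 20 RPM, and counts scaled to all aligned reads. The others, chosen after the results were seen, were repeats with flanks, repeats with tRNA trailers, coding spans only, ratios relative to the median gene, and gene totals and the share of other sequence without the flanks of centromere 3. The gene counts were tested on simulated data with 8-fold changes placed in 200 genes, fewer where too few had reads. These were genes with at least 50 expected antisense reads in the reference library. Where fewer than 50 genes had that many, the 200 with the highest antisense rate were taken. The runs therefore do not cover genes with few antisense reads. Of 100 simulated rises each, 100 were recovered for dis3-54,D171N and for dcr1Δ and 33 for wild type + ago1D580A, where 33 reached 50 reads, and for dcr1Δdis3-54,D171N against dcr1Δ 46 of 46. Of 100 simulated falls each against wild type, 12 reached 50 reads for dis3-54,D171N, 13 for dcr1Δ and 8 for wild type + ago1D580A, and 12, 13 and 7 were recovered, so most falls could not be called. For dcr1Δdis3-54,D171N against dcr1Δ 45 of 46 falls reached 50 reads and 45 were recovered. False calls could be judged in 1 of these runs only, dcr1Δdis3-54,D171N against dcr1Δ, where 0 of 235 unchanged genes were called, since at most 1 reached 50 reads in each of the others. With no gene changed, 0 of 134 genes were called for dis3-54,D171N, 0 of 60 for dcr1Δ, 0 of 16 for wild type + ago1D580A and 0 of 322 for dcr1Δdis3-54,D171N against dcr1Δ, for counting error alone. The mating-type cenH interval and mitochondrial RNA were not analysed here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and pyarrow 21.0.0.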

Results

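Small RNAs bound to Argonaute were sequenced from fission yeast (Schizosaccharomyces pombe) carrying Flag-tagged Ago1, the protein that holds small RNAs in RNA interference, on a pREP1 plasmid. Each of the 13 strains gave 1 library, so no difference has a replicate check and no test was run. The 12 comparisons with wild type share this 1 reference library. In each of them the sense median of all genes was higher, by 1.01 to 1.86 log2. Genes lower in several strains, such as vtc4, trm732 and mae1, may differ in that library, so their falls cannot be assigned to each strain. Depth ran from 1225697 aligned reads in wild type + ago1D580A to 6870265 in dcr1Δdis3-54,D171N. The others held 2907457 in wild type, 5238371 in rdp1Δ, 5384465 in dcr1Δ, 2094260 in cid12Δ, 3627919 in cid12Δ + nmt1-rdp1+ and 5434498 in clr4Δ. A further 4782599 were aligned in arb1Δ, 4020012 in arb2Δ, 6452443 in chp1Δ, 5611876 in swi6Δ and 5731590 in dis3-54,D171N. In 11 libraries at least 99.5% of reads were 18 to 30 nt long, against 83.2% in dis3-54,D171N and 93.6% in dcr1Δdis3-54,D171N. All 95% confidence intervals (CI) below are exact and cover counting error only, since reads carried no molecular identifiers. The dg/dh class is the outer repeats of the 3 centromeres, in 6 blocks such as centromere 3 left (chromosome III, 1071176 to 1092436) and right (chromosome III, 1106558 to 1139535). Single-gene log2 ratios are given after subtraction of the median sense log2 ratio of all 5113 protein-coding genes, whereas folds, bounds, list medians and ratios quoted with an interval are not shifted. They are scaled to the reads outside dg/dh, rRNA and tRNA, of which the flanks of centromere 3 held 197707 of 287920 in wild type, or 68.7%, and at most 3.55% in any other library. Without the flanks, unshifted folds and bounds against wild type come out 3.08 to 3.19 times lower where a gene was higher, and that many times larger where it was lower. Relative to the median gene a list median moves by the shift given for its comparison, which can turn its sign. List medians are also described by their percentile among 10000 random lists matched on level, as a description of these libraries.

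Reads in the coding span of each deleted gene were counted first, to check the labels. The genes cid12 (SPCC663.12, chromosome III, 1655669 to 1656679) and swi6 (SPAC664.01C, chromosome I, 1703015 to 1704001) had 0 reads in their own deletions, but wild type also had 0 at both. cid12Δ + nmt1-rdp1+ had 1 read in cid12, and at clr4 (SPBC428.08C, chromosome II, 456575 to 458047) there were 2 reads in clr4Δ against 0 to 40 elsewhere. arb1Δ had 1 read in arb1 (SPAC140.03, chromosome I, 1900052 to 1901431), where other libraries had 2 to 23. chp1 (SPAC18G6.02C, chromosome I, 2210977 to 2213859) had 3 in chp1Δ and 3 to 163 in the others. rdp1Δ kept 9 reads in rdp1 (SPAC6F12.09, chromosome I, 1325253 to 1328900), 8 of them in the downstream part of the coding span, and the others had 6 to 349. The 19 reads of arb2Δ in arb2 (SPAC13G7.07, chromosome I, 2309026 to 2310215) were all in the downstream part, and at 41.5 RPM lay above the other libraries at 0 to 31.4 RPM, which goes against the label if that part is deleted. In the upstream part arb2Δ had 0 reads and the others 0 to 5. At dcr1 (SPCC188.13C, chromosome III, 1506166 to 1510290) dcr1Δ had 46 reads, 45 of them at the 3′ end, and a count outside the deleted part checks nothing. The extent of each deletion is not in the labels. The library labelled dcr1Δdis3-54,D171N had 14 dcr1 reads upstream of that end, where dcr1Δ had 1 and wild type 0, which goes against its label if that part is deleted. At codon 580 of ago1, 2 of 2 reads coded for alanine in wild type + ago1D580A and 2 of 2 for aspartate in wild type. ago1 is on the plasmid in every library, so its level cannot be assigned to the strain. Both strands of it gave 420 RPM in wild type and 4389 to 19905 RPM elsewhere. rdp1 gave 154 reads in cid12Δ + nmt1-rdp1+ and 39 in cid12Δ. dis3 (SPBC26H8.10, chromosome II, 3970969 to 3974045) gave 198 reads in dis3-54,D171N, 176 in dcr1Δdis3-54,D171N and 3 in wild type, and a level cannot show the allele.

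In wild type, dg/dh repeats held 39.0% (95% CI, 39.0 to 39.1%) of aligned reads, from 4.35% in centromere 2 right to 12.9% in centromere 3 right. Fragments of ribosomal RNA held 49.5%, nearly all from the 3′ external transcribed spacer (3′ ETS), which is trimmed off the rRNA precursor and alone held 47.2%. The sequence TCTTGTTGGTAGGCAAAAAAT from this spacer made 11.9% of wild type reads. Protein-coding genes held 1.27% in sense and 0.248% in antisense, and the subtelomeric helicase genes tlh1 and tlh2 held 0.466%. tlh1 had 6779 reads and tlh2 6765, with 358 each in cid12Δ but 637 and 836 in clr4Δ. Such near-equal counts leave open whether the pair gives 2 separate measurements. Of dg/dh reads, 96.6% were 20 to 24 nt long and 93.8% began with U. The antisense share of gene reads was 16.3% (95% CI, 16 to 16.7%). Across the libraries, the plus strand of dg/dh gave between 44.6% of dg/dh reads in dcr1Δdis3-54,D171N and 51.4% in arb1Δ. The mating-type cenH interval was not analysed here.

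**Figure D1:**
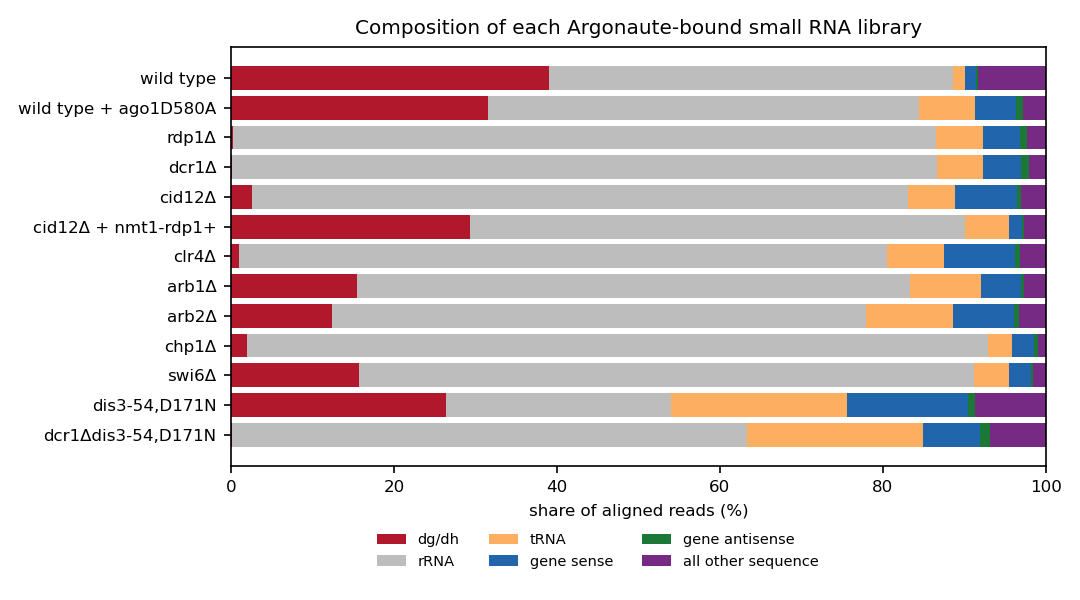
Share of aligned reads (%, x axis) in each class of RNA for the 13 libraries (y axis), as stacked bars. The dg/dh part goes from 39.0% in wild type to 0.0749% in dcr1Δdis3-54,D171N, and tRNA reaches 21.6% in dis3-54,D171N.

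**Figure D2:**
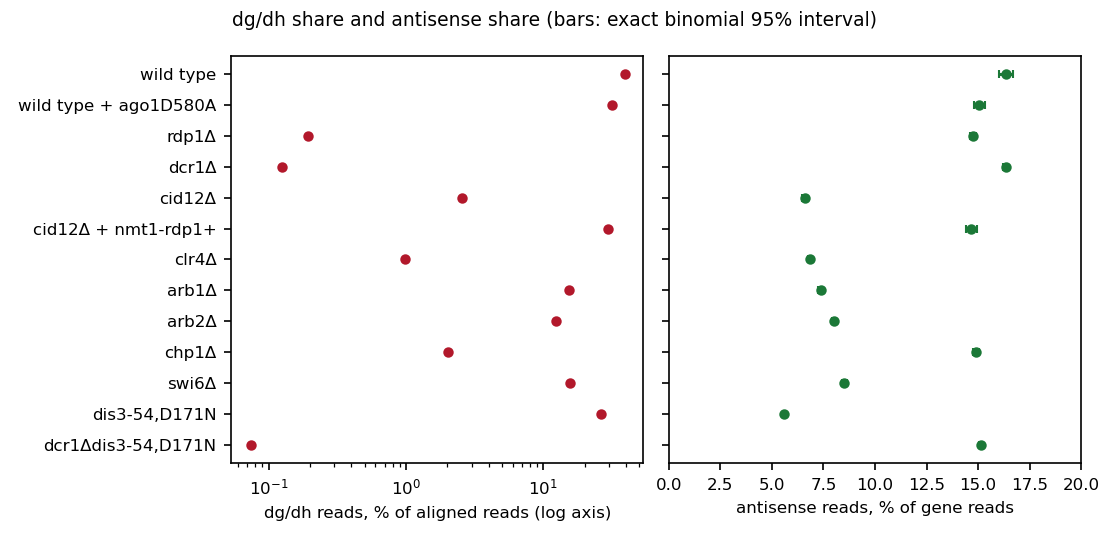
The dg/dh share of aligned reads (%, log axis) and the antisense share of gene reads (%) in each library, with exact binomial 95% intervals as bars. Antisense shares lie at 16.3% in wild type and dcr1Δ and at 5.58% in dis3-54,D171N.

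The comparison of rdp1Δ with wild type asks which Ago1-bound small RNAs remain without Rdp1, the RNA-directed RNA polymerase. dg/dh reads were 203-fold lower, at 0.193% (95% CI, 0.189 to 0.196%) of aligned reads. Antisense reads of tlh2 and tlh1, subtelomeric RecQ-type helicase genes, were 1521-fold and 691-fold lower, with 4 against 4343 and 9 against 4441 reads. In the other direction, antisense reads of pan1, an endocytosis gene, were 132 against 0, at least 31.4-fold higher or 9.85-fold without the flanks, and those of def1, which acts in the removal of stalled RNA polymerase II, were at least 19-fold higher. ura1, of pyrimidine synthesis, had 183 against 1, a log2 ratio of 7.03 (95% CI, 4.53 to 12.34), and trm732 had 11 against 144 with a relative log2 ratio of -5.70. Heat-shock genes had a median antisense log2 ratio of 2.40 (percentile 99.76, random lists 1.19), and thiamine and phosphate genes one of 2.81 (percentile 99.96, random lists 1.53). The 3′ ETS held 81.3% of reads. For rdp1Δ the dg/dh log2 ratio was -7.66 (95% CI, -7.69 to -7.64) and the antisense share of gene reads 14.8% (95% CI, 14.6 to 14.9%), a log2 ratio of -0.15 (95% CI, -0.18 to -0.11). With at least 50 antisense reads in the higher library, 83 genes were measured and 65 were over 4-fold higher and 5 lower. The median gene was shifted by 1.73 log2 in sense, and relative to it 21 genes were higher and 6 lower, or 12 and 5 scaled to all aligned reads and 34 and 6 without the flanks. Other ways of counting put the dg/dh log2 ratio between -9.36 (single-place reads only) and -4.90 (distinct sequences), and the antisense log2 ratio turned to 1.04 with perfect matches only.

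dcr1Δ against wild type asks which small RNAs Ago1 binds when Dicer, which cuts double-stranded RNA, is missing. A dg/dh share of 0.126% (95% CI, 0.123 to 0.129%) remained, 310-fold below wild type, in 6792 reads. Of these, 86.5% were 20 to 24 nt long and 85.2% began with U. Antisense reads of tlh1 (SPAC212.11, chromosome I, 1 to 5662) and tlh2 were 1598-fold and 1563-fold lower, with 4 reads each. pan1 (SPAC25G10.09C, chromosome I, 4313118 to 4318707) had 208 against 0 antisense reads, at least 48.2-fold higher or 15.1-fold without the flanks. Other genes with 0 antisense reads in wild type were def1 (at least 33.4-fold), met26, which codes for methionine synthase (at least 29.6-fold), mot1, an ATPase that acts on the TATA-binding protein (at least 27.1-fold), and fas1, a fatty acid synthase gene (at least 25.7-fold). bbc1 was at least 16-fold higher, dbp2 and SPAC29A4.02C at least 15.1-fold, while ura1 had 260 against 1 reads, a log2 ratio of 7.50 (95% CI, 5.01 to 12.81), and rex3 129 against 1, at 6.49 (95% CI, 3.98 to 11.80). Lower antisense counts, relative to the median gene, were found at trm732 (30 against 144, log2 -4.49), taf12 of the TFIID complex (17 against 76, -4.33) and vtc4, which makes polyphosphate (14 against 62, -4.29). In sense, SPAC11D3.14C was at least 18.3-fold higher, with log2 ratios of 6.07 (95% CI, 4.19 to 9.12) at pan1, 6.36 (95% CI, 3.85 to 11.67) at snf21, 5.71 (95% CI, 3.84 to 8.77) at rqt2 and 6.15 (95% CI, 3.64 to 11.46) at tsc1. aro1 had 193 against 209 sense reads, -2.42 relative to the median gene.

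Among the lists in dcr1Δ, antisense reads of the 16 genes of glycolysis and translation had a median log2 ratio of 2.66 (percentile 100, random lists 1.44). Thiamine and phosphate genes reached 2.96 (percentile 99.20, random lists 1.69), with 2 of 7 over 4-fold higher, nmt1 at 74 reads against 1 and bsu1 at 53 against 0. The 9 heat-shock genes stood at 2.44 (percentile 99.90, random lists 1.51) and in sense at 2.99 (percentile 99.94, random lists 2.14), where 8 of 9 were over 4-fold higher but 2 relative to the median gene. Ribosomal protein genes were at 0.97 in antisense (percentile 98.7) and histones at 1.51 (percentile 94.9). RNAi and heterochromatin factors lay at 1.13 (percentile 30.4), meiotic genes at 1.0 (percentile 20.4) and Tf2 retrotransposons at 1.77 (percentile 88.7). Relative to the median gene the antisense medians of these 5 lists fell below 0, to -0.81, -0.28, -0.65, -0.78 and -0.011 in turn. That shift is taken from sense reads, and the antisense median of all genes was 0.97. With a pseudocount of 1 RPM the percentile of histones fell to 34.5. Under other choices of processing the antisense percentiles of thiamine and phosphate genes and of ribosomal protein genes left the outer 2.5%, and that of Tf2 retrotransposons entered it. Of reads in Tf2 spans, 98% to 100% had several places in the genome in the 12 libraries other than wild type, so their 13 copies are not separate measurements, and pooled they had 72 against 3 antisense reads, a log2 ratio of 4.06 (95% CI, 2.45 to 6.37) or 2.28 relative to the median gene. The pair of tlh genes had a median of -10.02, below all random lists at percentile 0, but its 2 members may not be separate measurements. Opposite-strand partners that leave the 2-nt 3′ overhangs of a Dicer product were found for 1.65% of distinct dg/dh reads against 31.6% in wild type, and those percentages were 1.27 and 1.12 times the mean of the other overhangs. The most common overhang was another one in both, at 1 nt (33.4%) in wild type and -3 nt (1.79%) in dcr1Δ. The log2 ratio of the dg/dh share was -8.27 (95% CI, -8.31 to -8.24). The antisense share of gene reads, 16.3% (95% CI, 16.2 to 16.5%), differed from wild type by 0.00050 (95% CI, -0.035 to 0.036) log2, a difference not detectable at this depth. Of 136 genes measured in antisense, 117 were over 4-fold higher and 5 lower. The sense median of all genes was shifted by 1.78 log2; relative to it 55 genes were higher and 6 lower, scaled to all aligned reads 19 and 3, and without the flanks 79 and 6. Single-place reads only gave a dg/dh log2 ratio of -10.61 and whole centromeres -5.58, and perfect matches only gave an antisense log2 ratio of 1.26. Whole centromeres take in the tRNA genes of the imr, which held 31141 of the 37497 imr and cnt reads in dcr1Δ.

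Wild type + ago1D580A carried Ago1 changed in its slicer site, and the comparison with wild type asks what it binds. Whether intact ago1 remained is not in the labels. dg/dh repeats held 31.5% (95% CI, 31.4 to 31.6%) of reads, 1.24-fold below wild type. Their most common length was 24 nt against 23 nt, 74.1% were 20 to 24 nt long and 68.9% began with U. Partners with a 2-nt 3′ overhang were found for 37.5% of distinct dg/dh reads, 1.65 times the mean of the other overhangs, against 1.12 times in wild type. The plus strand held 49.5% of dg/dh reads against 50.7%. Antisense reads of tlh1 and tlh2 were 7.43-fold and 6.64-fold lower. Reads antisense to adh1, the main alcohol dehydrogenase gene (SPCC13B11.01, chromosome III, 1591292 to 1592889), were 1361 against 137, 26.6-fold higher or 8.36-fold without the flanks. Relative to the median gene, adh1 stood at a log2 ratio of 3.07, followed by mug2 (2.98), mug58 (2.57), the plasmid-borne ago1 (2.41), mtf2 (1.55), SPCC1739.01 (1.42) and spb1 (0.51). The next genes by raw ratio were gpi12, taf12 and ppa2, at -0.25, -0.96 and -1.49 relative to the median gene, which is taken from sense reads. The antisense median of all genes was lower, at 0.26 log2, and that of the 15 genes measured was 1.40. Lower counts were found at trm732 (-4.50) and mae1, the malate permease gene (-4.18), while vtc4 had 1 against 62, a log2 ratio of -4.53 (95% CI, -9.86 to -2.0). In sense, rpl35 (3.15), rpl301 (3.05), tif512 (2.91) and rpl26 (2.82) were higher, and 39 of the 42 ribosomal protein genes with 50 reads were over 4-fold higher, 11 of them relative to the median gene (list median 2.58, percentile 100, random lists 2.07). pyp3, a tyrosine phosphatase gene, had 53 against 3 sense reads, a log2 ratio of 5.57 (95% CI, 3.94 to 7.89). Sense reads were lower at aro1 (-2.68, 72.2% of them 1 sequence), ccr4 (-2.63) and mfs2 (-2.52). The log2 ratio of the dg/dh share was -0.31 (95% CI, -0.32 to -0.30); the antisense share of gene reads was 15% (95% CI, 14.8 to 15.3%), a log2 ratio of -0.12 (95% CI, -0.16 to -0.075). Among 15 genes measured, 7 were over 4-fold higher in antisense and 5 lower, with 4 and 5 relative to the median gene, which was shifted by 1.65 log2, 6 and 4 scaled to all aligned reads, and 4 and 5 without the flanks. With single-place reads only the dg/dh log2 ratio was -1.70, and without rRNA and tRNA it was -0.028. The antisense log2 ratio turned to 0.62 with perfect matches only and to 0.12 with coding spans only.

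cid12Δ lacks a nucleotidyltransferase that works with Rdp1, and its comparison with wild type asks whether dg/dh small RNAs need it. dg/dh repeats held 2.57% (95% CI, 2.55 to 2.59%) of reads, 15.2-fold below wild type. Over 200-nt bins these reads lay where those of wild type lay (variance to mean ratio 1.62). Wild type material in the sample, weighed below, may account for them. Antisense reads of tlh1 and tlh2 were 15.6-fold and 14-fold lower. Higher antisense counts stood at erm1 (523 against 2, log2 ratio 8.33, 95% CI 6.47 to 11.38), SPAC110.06 (266 against 1, 8.35, 95% CI 5.86 to 13.66) and rki1, of the pentose phosphate pathway (278 against 3, 6.83, 95% CI 5.27 to 9.12). A single sequence made 93.5%, 92.5% and 91% of these reads. vtc4 had 2 against 62, a log2 ratio of -4.66 (95% CI, -7.73 to -2.74). Sense reads of glycolysis and translation genes had a median log2 ratio of 4.03 (percentile 99.80, random lists 2.85), with 15 of 16 over 4-fold higher and 11 relative to the median gene. Sense rDNA outside the 3′ ETS held 40.0% of reads against 2.23% in wild type. The last base of dg/dh reads differed from the genome in 22.9% of reads against 26.6% in wild type, most often as A in both (14.4% and 13.6%). In log2, dg/dh differed by -3.93 (95% CI, -3.94 to -3.91), and the antisense share of gene reads was 6.59% (95% CI, 6.47 to 6.71%), a log2 ratio of -1.31 (95% CI, -1.35 to -1.27). Of 26 genes measured in antisense, 17 were over 4-fold higher and 5 lower. After the sense shift of 1.48 log2 was taken off, 12 were higher and 8 lower, scaled to all aligned reads 16 and 3, and without the flanks 12 and 8. Between single-place reads only and a total without rRNA and tRNA, the dg/dh log2 ratio moved from -4.65 to -2.10.

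cid12Δ + nmt1-rdp1+ expressed Rdp1 from the strong nmt1 promoter, and its comparisons ask whether extra Rdp1 restores dg/dh small RNAs without Cid12. Against cid12Δ, the dg/dh share was 11.4-fold higher at 29.3% (95% CI, 29.2 to 29.3%), and against wild type it was 1.33-fold lower. All 6 outer repeat blocks held reads, and the library's profile over centromere 3 is drawn beside that of wild type. Relative to cid12Δ, sense reads of the pair of tlh genes had a median log2 ratio of 3.85 (percentile 99.96, random lists -1.35) and antisense reads one of 2.77 (percentile 97.2). SPCC330.03C and SPCC622.04 had 88 against 0 and 76 against 0 antisense reads, at least 41.5-fold and 35.9-fold higher than cid12Δ, and mfs2, a transporter gene, had 90 against 5, 4.96 relative to the median gene. SPAC1B3.02C (0 against 606) and SPAC110.06 (0 against 266) were at least 143-fold and 62.6-fold lower, and erm1 had a log2 ratio of -8.53 (95% CI, -13.84 to -6.04). Sense reads of glycolysis and translation genes were lower than in cid12Δ, with a median of -2.46 (percentile 0.01, random lists -1.31) and 11 of 16 over 4-fold lower, 5 of them relative to the median gene. Histone genes had an antisense median of 2.68 against wild type (percentile 100, random lists 0.72). Against wild type, mfs2 was at least 52.2-fold higher or 16.6-fold without the flanks, SPCC330.03C had 88 against 1 at a log2 ratio of 7.26 (95% CI, 4.74 to 12.58), and the plasmid-borne ago1 stood at 2.40. Lower were vtc4 (1 against 62, log2 ratio -5.16, 95% CI -10.48 to -2.62), mae1 (3 against 69, -3.72, 95% CI -6.04 to -2.12) and tlh2 (-2.15). For dg/dh the log2 ratio was -0.41 (95% CI, -0.42 to -0.41) against wild type and 3.51 (95% CI, 3.50 to 3.52) against cid12Δ. Antisense reads made 14.7% (95% CI, 14.4 to 14.9%) of gene reads, a log2 ratio of -0.16 (95% CI, -0.20 to -0.11) against wild type and 1.15 (95% CI, 1.11 to 1.19) against cid12Δ. Of 15 genes measured against wild type, 5 were over 4-fold higher in antisense and 2 lower (3 and 4 relative to the median gene, shifted by 1.01 log2, 2 and 4 scaled to all aligned reads, and 2 and 5 without the flanks). Against cid12Δ, 8 of 26 were higher and 13 lower (9 and 12 relative to a median gene shifted by -0.58 log2, and 3 and 15 scaled to all aligned reads). Without rRNA and tRNA, the dg/dh log2 ratio against wild type turned to 0.12 and that against cid12Δ was 2.21. With perfect matches only, the antisense log2 ratio against wild type turned to 0.54.

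**Figure D3:**
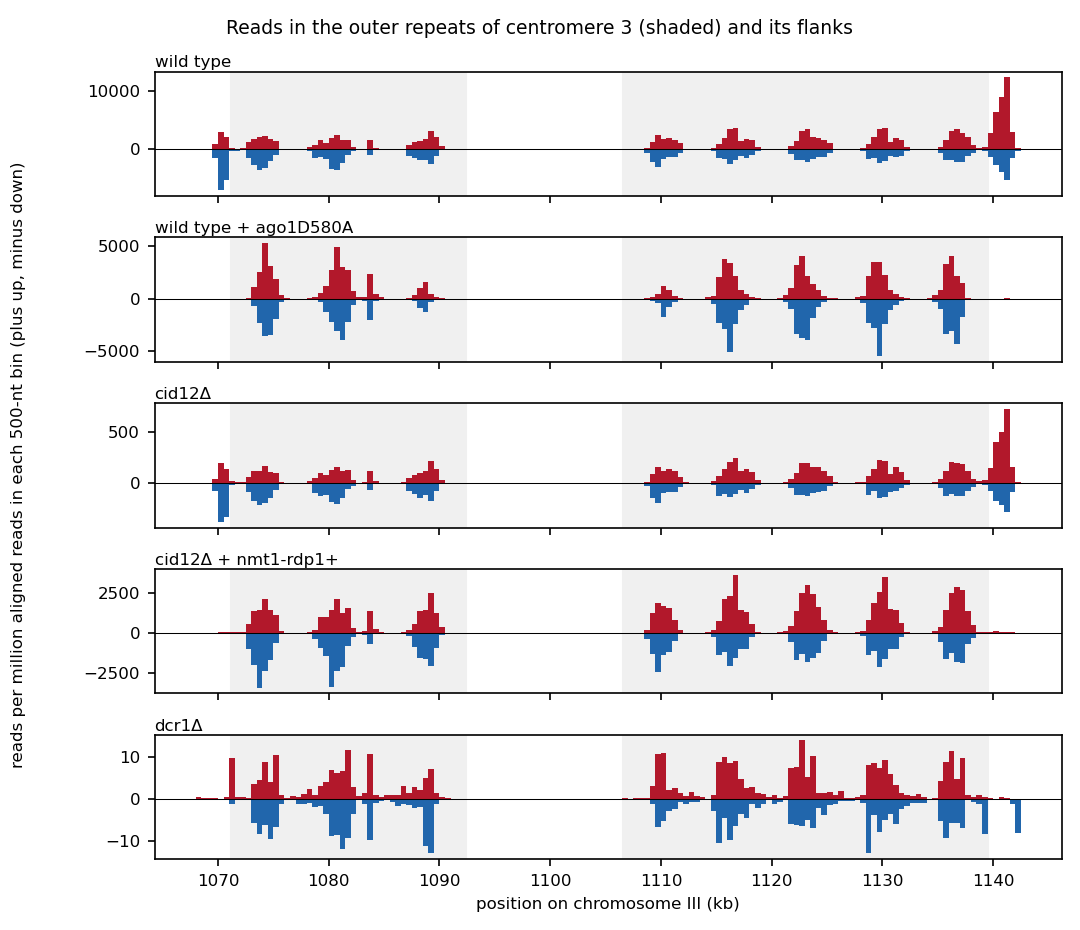
Reads (RPM of aligned reads, y axis, plus strand up and minus strand down, scale set per panel) in 500-nt bins along centromere 3 (x axis, kb on chromosome III) in wild type, wild type + ago1D580A, cid12Δ, cid12Δ + nmt1-rdp1+ and dcr1Δ, with the outer repeats shaded. Wild type has reads beyond the repeats as well, 6.80% of its aligned reads against 0.0576% in cid12Δ + nmt1-rdp1+.

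In clr4Δ, which lacks the histone H3 lysine 9 methyltransferase, the comparison with wild type asks how small RNAs depend on this mark of heterochromatin. The dg/dh share was 0.982% (95% CI, 0.974 to 0.991%), 39.7-fold below wild type, and antisense reads of tlh1 and tlh2 were 52.1-fold and 45.5-fold lower. ade6, of adenine synthesis (SPCC1322.13, chromosome III, 1316281 to 1318035), had 278 against 0 antisense reads, at least 39.1-fold higher or 12.3-fold without the flanks. bub1, a spindle checkpoint kinase gene beside it (SPCC1322.12C, chromosome III, 1312560 to 1315997), had 150 against 1, a log2 ratio of 5.98 (95% CI, 3.48 to 11.30). SPCC794.06 followed with 271 against 3 (5.25, 95% CI 3.69 to 7.54), and vtc4 was lower at -4.37 relative to the median gene. Tf2 copies pooled had 569 against 15 sense reads, a log2 ratio of 4.0 (95% CI, 3.27 to 4.85) or 2.25 relative to the median gene. Sense reads of glycolysis and translation genes had a median log2 ratio of 3.59 (percentile 99.81, random lists 2.47). Fragments of other abundant RNAs were higher too. Sense rDNA outside the 3′ ETS held 12.8% of reads against 2.23% in wild type, and snRNA and snoRNA 0.512% against 0.0460%. The log2 ratio for dg/dh was -5.31 (95% CI, -5.33 to -5.30), and the antisense share of gene reads 6.84% (95% CI, 6.77 to 6.91%), at -1.26 (95% CI, -1.29 to -1.22). Over 4-fold higher antisense counts were found in 19 of 52 genes and lower ones in 4; relative to the median gene (shifted by 1.75 log2) 8 were higher and 4 lower, scaled to all aligned reads 10 and 2, and without the flanks 9 and 4. Single-place reads only gave a dg/dh log2 ratio of -6.86, and a total without rRNA and tRNA one of -3.46.

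Chp1 is a chromodomain protein of the complex that ties Ago1 to heterochromatin, and chp1Δ against wild type asks what is bound without it. dg/dh repeats gave 2.01% (95% CI, 2.0 to 2.02%) of reads, 19.4-fold below wild type, while the 3′ ETS alone gave 87.7%. Antisense reads of tlh1 (20 against 4441) and tlh2 (21 against 4343) were 206-fold and 192-fold lower. pan1 was at least 41-fold higher in antisense, 12.9-fold without the flanks, and the kinase gene nnk1 at least 35.6-fold, ura1 had 168 against 1 (log2 ratio 7.50, 95% CI 5.01 to 12.82), and trm732 was at -5.34 relative to the median gene. Heat-shock genes stood at a sense median of 3.19 (percentile 99.97, random lists 2.26), with 9 of 9 over 4-fold higher but 1 relative to the median gene, and at 2.46 in antisense (percentile 99.92, random lists 1.39). The log2 ratio of dg/dh was -4.28 (95% CI, -4.29 to -4.27), and that of the antisense share, 14.9% (95% CI, 14.8 to 15.1%), was -0.13 (95% CI, -0.17 to -0.095). In antisense, 38 of 50 genes were over 4-fold higher and 5 lower, or 21 and 6 relative to a median gene shifted by 1.77 log2, 5 and 5 scaled to all aligned reads, and 24 and 6 without the flanks. Without rRNA and tRNA the dg/dh log2 ratio was -1.28, and the antisense log2 ratio turned to 1.15 with perfect matches only.

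Swi6 is a heterochromatin protein of the HP1 family that binds methylated histone H3, and the question for swi6Δ is whether small RNAs are bound without it. dg/dh reads made 15.7% (95% CI, 15.6 to 15.7%), 2.49-fold below wild type, and the tlh genes held 0.201% of aligned reads against 0.466%. Their antisense median log2 ratio was -0.17 (percentile 8.29, random lists 1.27), but -1.84 without the flanks and -1.30 scaled to all aligned reads. Relative to the median gene, antisense reads were higher at the plasmid-borne ago1 (152 against 16, 1.76), gep4 (52 against 5, 1.68) and gpi12, of GPI anchor synthesis and near a snoRNA gene (1.34). They were lower at taf12 (-4.44) and trm732 (-4.37), and vtc4 had 3 against 62, a log2 ratio of -4.18 (95% CI, -6.50 to -2.57). Tf2 copies pooled had 92 against 15 sense reads, a log2 ratio of 2.80 (95% CI, 2.01 to 3.70) or 1.24 relative to the median gene. The dg/dh log2 ratio was -1.32 (95% CI, -1.32 to -1.31); antisense reads made 8.52% (95% CI, 8.38 to 8.65%) of gene reads, at -0.94 (95% CI, -0.98 to -0.90). Of 17 genes, 7 were over 4-fold higher in antisense and 3 lower, but 0 and 4 relative to the median gene, shifted by 1.56 log2, 0 and 3 scaled to all aligned reads, and 0 and 4 without the flanks. Without rRNA and tRNA dg/dh was at -0.039 log2, and perfect matches only turned the antisense log2 ratio to 0.077.

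Arb1 and Arb2 bind Ago1 in a complex, and the libraries labelled arb1Δ and arb2Δ ask, against wild type, what Ago1 carries without either partner. Reads given above put the arb2Δ label in doubt only if their part of arb2 is deleted. dg/dh repeats held 15.4% (95% CI, 15.4 to 15.5%) in arb1Δ and 12.4% (95% CI, 12.4 to 12.5%) in arb2Δ, 2.53-fold and 3.14-fold below wild type. ura4, a pyrimidine synthesis gene (SPCC330.05C, chromosome III, 115589 to 116625), had 232 antisense reads in arb1Δ and 151 in arb2Δ against 3 in wild type, log2 ratios of 5.88 (95% CI, 4.31 to 8.17) and 4.98 (95% CI, 3.41 to 7.28), with no sequence above 7.28% of them. txc1 had 86 against 1 in arb1Δ (log2 ratio 6.03, 95% CI 3.52 to 11.35) and 123 against 1 in arb2Δ (log2 ratio 6.27, 95% CI 3.77 to 11.59), of which 1 sequence made 83.7% and 81.3%. zds1 had 99 against 2 in arb1Δ (log2 ratio 5.24, 95% CI 3.34 to 8.30), and ykt6, a vesicle fusion gene, was at least 17.6-fold higher in arb2Δ, 5.52-fold without the flanks, with 86.9% of its reads 1 sequence. In arb1Δ antisense reads were lower at mae1 (2 against 69, log2 ratio -5.50, 95% CI -8.58 to -3.60), vtc4 (-5.54) and tlh2 (-4.95). arb2Δ had lower reads at tlh1 (-7.32), tlh2 (-7.20) and vtc4 (-5.65). The dg/dh log2 ratios were -1.34 (95% CI, -1.34 to -1.34) and -1.65 (95% CI, -1.66 to -1.65). Antisense reads made 7.36% (95% CI, 7.26 to 7.46%) of gene reads in arb1Δ, at -1.15 (95% CI, -1.19 to -1.11) log2, and 8.0% (95% CI, 7.91 to 8.09%) in arb2Δ, at -1.03 (95% CI, -1.07 to -0.99). For arb1Δ, 23 of 37 genes were over 4-fold higher in antisense and 4 lower, 5 and 5 relative to a median gene shifted by 1.71 log2, 7 and 4 scaled to all aligned reads, and 6 and 5 without the flanks. For arb2Δ the counts were 34 and 4 of 52, 8 and 6 relative to a median gene shifted by 1.86, 15 and 4 scaled to all aligned reads, and 11 and 6 without the flanks. Without rRNA and tRNA the dg/dh log2 ratios were -0.27 and -0.61, and with single-place reads only -2.29 and -3.16.

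dis3-54,D171N carries a mutation in Dis3, the 3′-5′ exoribonuclease of the exosome, and its comparison with wild type asks what Ago1 binds when RNA breakdown is impaired. The library stood apart in its reads, which ran to 40 nt with 15.7% over 30 nt and 2.68% with an undetermined base, against at most 34 nt, 0.220% and 0.0587% in the 11 libraries without a dis3 mutation. tRNA held 21.6% of reads against 1.54%, and snRNA and snoRNA 1.94% against 0.0460%. Sense reads of genes made 14.9% against 1.27%, whereas dg/dh at 26.4% (95% CI, 26.4 to 26.4%) was 1.48-fold lower and the 3′ ETS held 5.73% against 47.2%. The most abundant sequence was the 28-nt tRNA fragment GCTTTGGTGGTTTAGTGGTATAATGAAT, at 3.16% of reads. Antisense to pof2, an F-box gene (SPBC25B2.11, chromosome II, 2617862 to 2619476), there were 972 against 0 reads, at least 66.7-fold higher or 21-fold without the flanks. rim2, a mitochondrial carrier gene (at least 36.4-fold, 80.4% of it 1 sequence), git11, a G-protein subunit gene beside a tRNA gene (at least 35.8-fold), dph7 (at least 13-fold), tom20 (at least 12.6-fold) and csc1 (at least 10.4-fold) had 0 reads in wild type. Without the flanks these bounds were 11.5, 11.3, 4.11, 3.98 and 3.29. mpe1, of mRNA cleavage and polyadenylation, stood at 3.87 relative to the median gene. tif211, which codes for a subunit of translation factor eIF2, had 477 against 2 reads (log2 ratio 5.62, 95% CI 3.76 to 8.67), lcf2 463 against 2 (5.57, 95% CI 3.71 to 8.62) and mug115 448 against 2 (5.53, 95% CI 3.66 to 8.58). Antisense reads were lower, relative to the median gene, at trm732 (-5.33), vtc4 (-4.53), gpi12 (-3.01), SPAC212.06C (-2.97) and mtf2 (-2.69). Of sense reads, tef102, an elongation factor gene, had 3789 against 6 (5.45) and the ribosomal protein gene rps801 2032 against 4 (5.01). rps2502 had 1137 against 1 (log2 ratio 7.87, 95% CI 5.39 to 13.17), rps1202 1683 against 3 (6.85, 95% CI 5.30 to 9.13) and sua1, which codes for ATP sulfurylase, 854 against 1 (7.46, 95% CI 4.97 to 12.76). SPBC530.02 and mfs2 were both at -3.62 in sense, SPAC212.06C at -3.15, ssr3 at -2.77 and tom5 at -2.68.

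Of the 138 ribosomal protein genes with 50 sense reads in dis3-54,D171N, 121 were over 4-fold higher than wild type and 76 relative to the median gene (list median 3.35, percentile 100, random lists 2.37). Tf2 copies pooled had 775 against 15 sense reads, a log2 ratio of 3.41 (95% CI, 2.68 to 4.25) or 2.15 relative to the median gene. Glycolysis and translation genes stood at 3.47 (percentile 87.9, 13 of 16 over 4-fold higher), histones at 2.78 (percentile 93.9, 9 of 10), heat-shock genes at 2.31 (percentile 28.7, 5 of 9) and thiamine and phosphate genes at 2.06 (percentile 10.0, 4 of 7). Relative to the median gene these 4 counts were 9, 4, 0 and 0. Meiotic genes, whose transcripts the exosome clears in growing cells, had a sense median of 0.35 (percentile 7.91), -0.91 relative to the median gene, with mug8 at 53 reads against 0. RNAi and heterochromatin factors were at 1.27 in sense (percentile 57.1) and -0.46 in antisense (percentile 1.86), and tlh genes at -0.59 (percentile 0.29) and -0.75 (percentile 11.3), the last pair turning to 0.70 and 0.55 scaled to all aligned reads. Sense gene reads were 20 to 24 nt long in 35.1% and began with U in 19.1%, against 92.8% and 52.4% in wild type. The dg/dh log2 ratio was -0.56 (95% CI, -0.57 to -0.56), and antisense reads made 5.58% (95% CI, 5.53 to 5.62%) of gene reads, at -1.55 (95% CI, -1.59 to -1.51) log2. Antisense counts were over 4-fold higher in 98 of 155 genes and lower in 2, in 39 and 8 relative to a median gene shifted by 1.26 log2, in 59 and 1 scaled to all aligned reads, and in 50 and 11 without the flanks. Counting 20 to 24 nt reads only turned the dg/dh log2 ratio to 0.27, while single-place reads only gave -2.85. The antisense log2 ratio lay between -2.71 with coding spans only and -0.89 with 20 to 24 nt reads only.

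The library labelled dcr1Δdis3-54,D171N stands for both changes together, and against dcr1Δ it asks what Ago1 binds without Dicer when Dis3 is also mutated. Its reads ran to 40 nt as well, with 5.04% over 30 nt and 1.77% with an undetermined base. tRNA held 21.6% of reads against 5.68%, and dg/dh, at 0.0749% (95% CI, 0.0729 to 0.0770%), was 1.68-fold lower. Relative to the median gene, antisense reads were higher at SPAP27G11.14C (1910 against 11, 6.49, 99% of it 1 sequence), rim2 (6.43), tif211 (2119 against 18, 6.02), msa1 (5.96) and SPCC191.05C (5.88). SPAPB15E9.02C had 1085 against 3 (log2 ratio 7.18, 95% CI 5.63 to 9.46), git11 1019 against 3 (7.09, 95% CI 5.54 to 9.37) and pmo25 397 against 1 (7.31, 95% CI 4.83 to 12.62), while ppn1 was at least 43.4-fold higher and och1, a mannosyltransferase gene, at least 27.1-fold. Lower were rex3 (-3.40), tif301 (-3.36), tfg3 (-3.29), tom70 (-3.26) and brr2, a spliceosomal helicase gene (-3.21). Sense reads were higher at SPAC1952.10C (6.55), the fluoride exporter gene fex1 (6.12), pyp3 (5.26), mrpl51 (5.04) and SPBC36.02C (4.86). They were lower at mug108 (-2.83), top2, of topoisomerase II (-2.55), the metallothionein gene zym1 (-2.53), erg32 (-2.43) and esf2 (-2.22). Heat-shock genes had an antisense median of -2.38 (percentile 0.01, random lists -1.01) and a sense median of -1.25 (percentile 0.18, random lists -0.050). Ribosomal protein genes stood at 0.35 in sense (percentile 100, random lists -0.51) and the pair of tlh genes at 2.70 in antisense (percentile 99.37, random lists -1.23). The tlh percentile left the outer 2.5% under another choice of processing. The dg/dh log2 ratio was -0.75 (95% CI, -0.80 to -0.70), and the antisense share of gene reads was 15.1% (95% CI, 15 to 15.2%), at -0.11 (95% CI, -0.13 to -0.094) log2. Of 327 genes measured, 105 were over 4-fold higher in antisense and 96 lower, 134 and 63 relative to a median gene shifted by -0.62 log2, and 72 and 2 scaled to all aligned reads. With whole centromeres the dg/dh log2 ratio turned to 1.44, and without rRNA and tRNA it was -1.70. Whole centromeres take in the tRNA genes of the imr. These held 137287 of the 147998 imr and cnt reads here and 31141 of 37497 in dcr1Δ, so the turn does not show more repeat reads. The antisense log2 ratio turned to 0.23 with 20 to 24 nt reads only and reached -1.34 with coding spans only.

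Set against wild type and against dis3-54,D171N, the library labelled dcr1Δdis3-54,D171N asks what both changes give together and what the loss of Dicer adds. dg/dh was 521-fold below wild type and 352-fold below dis3-54,D171N. tRNA held 21.6% here and 21.6% in dis3-54,D171N, and sense gene reads 6.92% and 14.9%. Against wild type, antisense reads of pof2 (1283 against 0) and git11 (1019 against 0) were at least 119-fold and 94.5-fold higher, 37.3-fold and 29.6-fold without the flanks, and tif211 had 2119 against 2 (log2 ratio 8.20, 95% CI 6.35 to 11.25). tlh1, tlh2 and mae1 were lower, at -8.78, -8.08 and -4.50 relative to the median gene. Against dis3-54,D171N, ura1 had 59 against 1 (log2 ratio 6.32, 95% CI 3.78 to 11.65), txc1 stood at 3.39 and shm1, of one-carbon metabolism, at 3.36. tlh1 (73 against 11433, -6.56), tlh2 (-6.19) and csc1 (-3.48) were lower. Ribosomal protein genes had a sense median of -0.94 against dis3-54,D171N (percentile 0, random lists -0.52), and glycolysis and translation genes an antisense median of 0.95 (percentile 100, random lists 0.29). The dg/dh log2 ratios were -9.03 (95% CI, -9.06 to -8.99) against wild type and -8.46 (95% CI, -8.50 to -8.42) against dis3-54,D171N, and those of the antisense share were -0.11 (95% CI, -0.14 to -0.075) and 1.44 (95% CI, 1.42 to 1.46). Against wild type 166 of 234 genes were over 4-fold higher in antisense and 5 lower, 103 and 6 relative to a median gene shifted by 1.11 log2, 87 and 2 scaled to all aligned reads, and 100 and 6 without the flanks. Against dis3-54,D171N the counts were 65 and 11 of 265, 89 and 11 relative to a median gene shifted by -0.20, and 0 and 7 scaled to all aligned reads. Whole centromeres, which take in the tRNA genes of the imr, moved the dg/dh log2 ratios to -4.14 and -3.63. Against wild type the antisense log2 ratio turned to 0.16 with 20 to 24 nt reads only and was -1.11 with coding spans only.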

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

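All tests in this part were chosen after the results were seen.

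One pattern is that the dg/dh reads of cid12Δ lay where those of wild type lay: over 200-nt bins the variance to mean ratio between both libraries was 1.62, against 5.56 to 54.8 between cid12Δ and the 8 other libraries with at least 50000 dg/dh reads and 0.956 between 2 draws from wild type. Libraries of different labels can lie about as close, since the ratio between arb1Δ and arb2Δ was 1.88, although the arb2Δ label is open. Sequenced wild type reads as the source of all dg/dh reads in the cid12Δ library are argued against, because 2.97% of its dg/dh reads ended in a mismatched C, below the 5.56% of wild type by more than both counting intervals. Such reads as a part of them stay open, since the other 11 libraries gave 0.347% to 1.48%, below cid12Δ. A mismatched C was more frequent in other reads of cid12Δ too, at 1.24% of the 3′ ETS against 0.116% to 0.586% in those libraries and at 1.81% of tRNA trailers against 0.0581% to 0.5002%. Wild type reads would bring at most 0.384 and 0.178 of these percentage points if they were all dg/dh reads of cid12Δ, so the raised share was at least partly the library's own. Wild type cells, RNA or amplified product in the cid12Δ sample may still account for it, as the flanks of centromere 3 gave 15.5 reads per 100 dg/dh reads in cid12Δ and 17.4 in wild type, against 0.0152 to 2.93 in the other 11 libraries and 0.196 in cid12Δ + nmt1-rdp1+ among them. Small RNA production that remains without Cid12, the biological explanation, cannot be told apart from this, since the ratio of 1.62 lies above the value of repeated draws and near that of arb1Δ and arb2Δ. The only other library without cid12 also expressed nmt1-rdp1+, so it does not decide this.

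Another pattern is a signal that neither main ratio counts as dg/dh or gene reads, reads in the flanks of centromere 3 beyond the outer repeats (chromosome III, 1068176 to 1071175 and 1139536 to 1142535), which made 6.80% of aligned reads in wild type. They do enter the scaling of single genes, as 68.7% of the wild type reads outside dg/dh, rRNA and tRNA, and without them the sense median of all genes against wild type went from 1.65 to 0.32 log2 in wild type + ago1D580A and from 1.78 to 0.48 in dcr1Δ. Reads shared with other repeats do not account for all of it, because 43.9% of these flank reads have a single place in the genome. For the flank reads with several places, sharing stays open. A difference in depth is argued against too, as wild type + ago1D580A gave 0.0326 flank reads per 100 dg/dh reads. No biological explanation was tested, since the labels name nothing that sets the wild type strain apart at this site.

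A further pattern is the antisense signal of ura4 in the libraries labelled arb1Δ and arb2Δ, the second of which has reads in arb2 that go against its label if that part is deleted. A few amplified sequences are argued against, because no single sequence made more than 7.28% of these reads. Breakdown of ura4 mRNA would give sense reads, so the antisense share cannot test it. That share was 20.3% of ura4 reads in arb1Δ and 17.8% in arb2Δ, against 7.36% and 8.0% for all genes. It was also raised in swi6Δ (52.8%, 19 of 36 reads) and cid12Δ + nmt1-rdp1+ (61.1%, 11 of 18). A candidate explanation left open is another ura4 copy inside heterochromatin, as at least 93.4% of ura4 reads in both libraries began with U and at least that share was 20 to 24 nt long. The labels name no reporter gene, and no table here decides it.

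Other results stood out because a change went opposite ways in both backgrounds, and these differences were not tested. They rest on the library labelled dcr1Δdis3-54,D171N, whose 14 dcr1 reads upstream of the 3′ end go against that label if that part is deleted, so the backgrounds below are those of the labels. The Tf2 and LTR share of aligned reads differed by a log2 ratio of 2.85 between dis3-54,D171N and wild type, and of -0.75 between dcr1Δdis3-54,D171N and dcr1Δ. For the share of other sequence these ratios were -0.66 and 1.79, but the flanks of centromere 3 made 88.4% of it in wild type. Without them the ratios were 2.38 and 1.79, no longer opposite. snRNA and snoRNA reads differed by 1.37 between dcr1Δ and wild type and by -2.34 between dcr1Δdis3-54,D171N and dis3-54,D171N. In that order, the Tf2 and LTR share differed by 2.44 and -1.15, and the sense gene share by 1.88 and -1.10. The share of other sequence differed by -2.61 and -0.16 there, and by 0.49 and -0.10 without the flanks.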

How the results depend on the processing

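Of the alternatives below, repeats with flanks, repeats with tRNA trailers, coding spans only, ratios relative to the median gene and totals without the flanks of centromere 3 were chosen after the results were seen. Of 120 alternative values for the dg/dh log2 ratio, 9 stayed within the counting interval, 108 moved without a change of direction and 3 turned. For the antisense log2 ratio 12 of 75 stayed, 48 moved and 15 turned, among them swi6Δ, whose main value was -0.94. Single named genes stayed in 626 of 820 cases, moved in 187 and turned in 7, and list percentiles, run for 4 comparisons only, stayed within or outside the outer 2.5% at either end in 271 of 288 and moved in 17. The largest shifts of a percentile were 60.4 with a pseudocount of 1 RPM (histones antisense in dcr1Δ, 94.9 to 34.5), 32.6 with a pseudocount of 20 RPM (meiotic genes sense in dcr1Δ, 58.6 to 91.3), 36.7 with counts scaled to all aligned reads (RNAi and heterochromatin factors sense in dis3-54,D171N, 57.1 to 20.4) and 49.2 with totals without the flanks (meiotic genes antisense in wild type + ago1D580A, 50.4 to 1.21). Those that moved into or out of the outer 2.5% were in dis3-54,D171N RNAi and heterochromatin factors antisense (1.86 to 6.33) and meiotic genes sense (7.91 to 2.21). For dcr1Δ this held of ribosomal proteins antisense (98.7 to 96.1 or 95.6), thiamine and phosphate antisense (99.20 to 91.8), Tf2 retrotransposons antisense (88.7 to 97.7 or 98.6) and histones sense (97.4 to 98.2 or 98.6). For dcr1Δdis3-54,D171N against dcr1Δ this held of thiamine and phosphate antisense (1.98 to 4.21 or 2.77), Tf2 retrotransposons antisense (6.61 to 2.48), tlh genes antisense (99.37 to 88.7) and meiotic genes sense (3.77 to 0.47). For wild type + ago1D580A this held of histones antisense (95.1 to 99.74 or 99.67) and meiotic genes antisense (50.4 to 1.21). A library name alone stands for its comparison with wild type, or for its own value where no comparison is made. Genes that reached 50 antisense reads numbered 15 for wild type + ago1D580A, the library of least depth, but also 15 for cid12Δ + nmt1-rdp1+ and 17 for swi6Δ, against 26 for cid12Δ, so their number did not follow depth alone. Depth limits single genes with 0 reads in wild type, where the floor of 3 counts stands for 10.4 RPM, or 33.3 RPM without the flanks of centromere 3. Against wild type it also limits genes called lower, since of 100 simulated 8-fold falls 12 reached 50 reads for dis3-54,D171N, 13 for dcr1Δ and 8 for wild type + ago1D580A.

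Only reads of 20 to 24 nt gave the dg/dh log2 ratio as -9.34 in dcr1Δdis3-54,D171N against dis3-54,D171N, -9.07 in dcr1Δdis3-54,D171N, -8.41 in dcr1Δ, -7.78 in rdp1Δ, -4.30 in chp1Δ, -3.75 in cid12Δ and -1.62 in arb2Δ. arb1Δ was at -1.36, swi6Δ at -1.33, dcr1Δdis3-54,D171N against dcr1Δ at -0.67, wild type + ago1D580A at -0.55, cid12Δ + nmt1-rdp1+ at -0.40, dis3-54,D171N at 0.27 and cid12Δ + nmt1-rdp1+ against cid12Δ at 3.35. Directions turned here in dis3-54,D171N. For the antisense share the log2 ratio was -1.63 in cid12Δ, -0.89 in dis3-54,D171N, -0.22 in rdp1Δ, -0.066 in dcr1Δ, 0.16 in dcr1Δdis3-54,D171N, 0.23 in dcr1Δdis3-54,D171N against dcr1Δ, 1.05 in dcr1Δdis3-54,D171N against dis3-54,D171N and 1.51 in cid12Δ + nmt1-rdp1+ against cid12Δ. Turned in direction were dcr1Δdis3-54,D171N and dcr1Δdis3-54,D171N against dcr1Δ.

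Distinct sequences gave the dg/dh log2 ratio as -7.04 in dcr1Δdis3-54,D171N, -5.64 in dcr1Δ, -5.17 in dcr1Δdis3-54,D171N against dis3-54,D171N, -4.90 in rdp1Δ, -4.13 in clr4Δ, -2.79 in cid12Δ and -2.49 in chp1Δ. dis3-54,D171N was at -1.87, arb2Δ at -1.86, dcr1Δdis3-54,D171N against dcr1Δ at -1.40, arb1Δ at -1.23, swi6Δ at -0.80, wild type + ago1D580A at -0.52, cid12Δ + nmt1-rdp1+ at -0.35 and cid12Δ + nmt1-rdp1+ against cid12Δ at 2.43. For the antisense share the log2 ratio was -2.01 in dis3-54,D171N, -1.61 in cid12Δ, -0.70 in swi6Δ, -0.69 in dcr1Δdis3-54,D171N against dcr1Δ, -0.48 in dcr1Δdis3-54,D171N, -0.075 in wild type + ago1D580A and -0.052 in cid12Δ + nmt1-rdp1+. rdp1Δ was at 0.059, chp1Δ at 0.081, dcr1Δ at 0.21, dcr1Δdis3-54,D171N against dis3-54,D171N at 1.52 and cid12Δ + nmt1-rdp1+ against cid12Δ at 1.56. Turned in direction were rdp1Δ and chp1Δ. Reads beginning with U made up, in percent of dg/dh reads, 61.1 in wild type + ago1D580A, 62.6 in dcr1Δdis3-54,D171N, 67.6 in dis3-54,D171N, 73.1 in clr4Δ, 78.2 in arb1Δ, 80.4 in dcr1Δ and 80.7 in arb2Δ. wild type was at 84.1, swi6Δ at 85.9, cid12Δ + nmt1-rdp1+ at 86.2, rdp1Δ at 86.5, chp1Δ at 88.7 and cid12Δ at 89.95. The plus strand held, in percent, 42.0 in dis3-54,D171N, 43.2 in dcr1Δdis3-54,D171N, 48.9 in swi6Δ, 49.2 in chp1Δ, 49.8 in wild type + ago1D580A, 50.1 in clr4Δ and 50.2 in wild type. cid12Δ + nmt1-rdp1+ was at 50.2, arb2Δ at 50.4 and arb1Δ at 50.8.

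Perfect matches only gave the dg/dh log2 ratio as -8.10 in dcr1Δ, -7.51 in rdp1Δ, -5.27 in clr4Δ, -4.23 in chp1Δ, -4.13 in cid12Δ, -1.44 in arb2Δ and -1.27 in swi6Δ. arb1Δ was at -1.24, dcr1Δdis3-54,D171N against dcr1Δ at -0.95, dis3-54,D171N at -0.61, wild type + ago1D580A at -0.36, cid12Δ + nmt1-rdp1+ at -0.35 and cid12Δ + nmt1-rdp1+ against cid12Δ at 3.77. For the antisense share the log2 ratio was -1.72 in dis3-54,D171N, -1.13 in dcr1Δdis3-54,D171N against dcr1Δ, -0.98 in cid12Δ, -0.67 in clr4Δ, -0.57 in arb1Δ, -0.42 in arb2Δ and 0.077 in swi6Δ. dcr1Δdis3-54,D171N was at 0.12, cid12Δ + nmt1-rdp1+ at 0.54, wild type + ago1D580A at 0.62, rdp1Δ at 1.04, chp1Δ at 1.15, dcr1Δ at 1.26, cid12Δ + nmt1-rdp1+ against cid12Δ at 1.52 and dcr1Δdis3-54,D171N against dis3-54,D171N at 1.84. Turned in direction were swi6Δ, dcr1Δdis3-54,D171N, cid12Δ + nmt1-rdp1+, wild type + ago1D580A, rdp1Δ and chp1Δ.

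Single-place reads only gave the dg/dh log2 ratio as -10.82 in dcr1Δdis3-54,D171N, -10.61 in dcr1Δ, -9.36 in rdp1Δ, -7.97 in dcr1Δdis3-54,D171N against dis3-54,D171N, -6.86 in clr4Δ, -4.65 in cid12Δ and -4.02 in chp1Δ. arb2Δ was at -3.16, dis3-54,D171N at -2.85, arb1Δ at -2.29, wild type + ago1D580A at -1.70, swi6Δ at -0.74, cid12Δ + nmt1-rdp1+ at -0.43, dcr1Δdis3-54,D171N against dcr1Δ at -0.21 and cid12Δ + nmt1-rdp1+ against cid12Δ at 4.22. For the antisense share the log2 ratio was -1.64 in dis3-54,D171N, -1.17 in cid12Δ, -1.15 in clr4Δ, -1.08 in arb1Δ, -0.99 in arb2Δ, -0.80 in swi6Δ and -0.58 in dcr1Δdis3-54,D171N against dcr1Δ. dcr1Δdis3-54,D171N was at -0.39, cid12Δ + nmt1-rdp1+ at -0.076, rdp1Δ at 0.014, chp1Δ at 0.068, dcr1Δ at 0.19, cid12Δ + nmt1-rdp1+ against cid12Δ at 1.10 and dcr1Δdis3-54,D171N against dis3-54,D171N at 1.25. Turned in direction were rdp1Δ and chp1Δ.

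A total without rRNA and tRNA gave the dg/dh log2 ratio as -7.33 in dcr1Δdis3-54,D171N, -6.71 in dcr1Δdis3-54,D171N against dis3-54,D171N, -5.63 in dcr1Δ, -5.03 in rdp1Δ, -3.46 in clr4Δ, -2.10 in cid12Δ and -1.70 in dcr1Δdis3-54,D171N against dcr1Δ. chp1Δ was at -1.28, dis3-54,D171N at -0.62, arb2Δ at -0.61, arb1Δ at -0.27, swi6Δ at -0.039, wild type + ago1D580A at -0.028, cid12Δ + nmt1-rdp1+ at 0.12 and cid12Δ + nmt1-rdp1+ against cid12Δ at 2.21. Directions turned here in cid12Δ + nmt1-rdp1+.

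Whole centromeres gave the dg/dh log2 ratio as -5.58 in dcr1Δ, -5.14 in rdp1Δ, -4.45 in clr4Δ, -4.14 in dcr1Δdis3-54,D171N, -4.12 in chp1Δ, -3.72 in cid12Δ and -3.63 in dcr1Δdis3-54,D171N against dis3-54,D171N. arb2Δ was at -1.54, swi6Δ at -1.29, arb1Δ at -1.26, dis3-54,D171N at -0.51, cid12Δ + nmt1-rdp1+ at -0.38, wild type + ago1D580A at -0.28, dcr1Δdis3-54,D171N against dcr1Δ at 1.44 and cid12Δ + nmt1-rdp1+ against cid12Δ at 3.34. Directions turned here in dcr1Δdis3-54,D171N against dcr1Δ. In both libraries most imr and cnt reads lay in tRNA genes of the imr.

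Repeats with flanks, an added alternative, gave the dg/dh log2 ratio as -8.44 in dcr1Δdis3-54,D171N, -7.96 in dcr1Δ, -7.66 in dcr1Δdis3-54,D171N against dis3-54,D171N, -7.36 in rdp1Δ, -5.51 in clr4Δ, -4.50 in chp1Δ and -3.95 in cid12Δ. arb2Δ was at -1.88, arb1Δ at -1.57, swi6Δ at -1.55, dis3-54,D171N at -0.79, cid12Δ + nmt1-rdp1+ at -0.64, wild type + ago1D580A at -0.54, dcr1Δdis3-54,D171N against dcr1Δ at -0.48 and cid12Δ + nmt1-rdp1+ against cid12Δ at 3.31.

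Repeats with tRNA trailers, also added, gave the dg/dh log2 ratio as -8.20 in dcr1Δdis3-54,D171N, -7.63 in dcr1Δdis3-54,D171N against dis3-54,D171N, -7.32 in dcr1Δ, -6.94 in rdp1Δ, -5.24 in clr4Δ, -4.24 in chp1Δ and -1.64 in arb2Δ. arb1Δ was at -1.33 and dcr1Δdis3-54,D171N against dcr1Δ at -0.87.

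Coding spans only, an added alternative, gave the antisense log2 ratio as -2.71 in dis3-54,D171N, -1.98 in cid12Δ, -1.95 in clr4Δ, -1.34 in dcr1Δdis3-54,D171N against dcr1Δ, -1.12 in arb2Δ, -1.11 in dcr1Δdis3-54,D171N and -0.75 in swi6Δ. cid12Δ + nmt1-rdp1+ was at -0.35, rdp1Δ at 0.076, wild type + ago1D580A at 0.12, chp1Δ at 0.14, dcr1Δ at 0.23, dcr1Δdis3-54,D171N against dis3-54,D171N at 1.60 and cid12Δ + nmt1-rdp1+ against cid12Δ at 1.63. Turned in direction were rdp1Δ, wild type + ago1D580A and chp1Δ.

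A minimum of 20 reads gave the count of genes higher in antisense as 17 in cid12Δ + nmt1-rdp1+, 24 in cid12Δ + nmt1-rdp1+ against cid12Δ, 31 in wild type + ago1D580A, 37 in cid12Δ, 46 in swi6Δ, 65 in arb1Δ and 97 in clr4Δ. arb2Δ was at 99, chp1Δ at 220, dcr1Δdis3-54,D171N at 259, rdp1Δ at 321 and dcr1Δ at 435. Genes lower in antisense numbered 4 in cid12Δ + nmt1-rdp1+, 8 in arb1Δ, 8 in swi6Δ, 9 in arb2Δ, 9 in chp1Δ, 9 in clr4Δ and 9 in rdp1Δ. wild type + ago1D580A was at 9, dcr1Δ at 10, dcr1Δdis3-54,D171N at 10, dis3-54,D171N at 11, cid12Δ at 15, cid12Δ + nmt1-rdp1+ against cid12Δ at 27 and dcr1Δdis3-54,D171N against dcr1Δ at 314.

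No minimum of reads gave the count of genes higher in antisense as 166 in arb1Δ, 185 in clr4Δ, 236 in cid12Δ, 244 in arb2Δ, 277 in swi6Δ, 289 in dcr1Δdis3-54,D171N and 412 in cid12Δ + nmt1-rdp1+. cid12Δ + nmt1-rdp1+ against cid12Δ was at 445, wild type + ago1D580A at 783, rdp1Δ at 802, chp1Δ at 868 and dcr1Δ at 1046. Genes lower in antisense numbered 22 in rdp1Δ, 23 in dcr1Δ, 24 in chp1Δ, 24 in clr4Δ, 25 in cid12Δ + nmt1-rdp1+, 28 in arb2Δ and 28 in dcr1Δdis3-54,D171N. swi6Δ was at 34, arb1Δ at 35, wild type + ago1D580A at 36, dis3-54,D171N at 38, cid12Δ at 80, cid12Δ + nmt1-rdp1+ against cid12Δ at 137 and dcr1Δdis3-54,D171N against dcr1Δ at 547.

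Counts scaled to all aligned reads gave the count of genes higher in antisense as 0 in dcr1Δdis3-54,D171N against dis3-54,D171N, 0 in swi6Δ, 2 in cid12Δ + nmt1-rdp1+, 3 in cid12Δ + nmt1-rdp1+ against cid12Δ, 5 in chp1Δ, 7 in arb1Δ and 10 in clr4Δ. rdp1Δ was at 12, arb2Δ at 15, dcr1Δ at 19, dis3-54,D171N at 59 and dcr1Δdis3-54,D171N at 87. Genes lower in antisense numbered 1 in dis3-54,D171N, 2 in clr4Δ, 2 in dcr1Δdis3-54,D171N against dcr1Δ, 2 in dcr1Δdis3-54,D171N, 3 in cid12Δ, 3 in dcr1Δ, 4 in cid12Δ + nmt1-rdp1+ and 7 in dcr1Δdis3-54,D171N against dis3-54,D171N. Antisense log2 ratios of single genes in wild type + ago1D580A were -0.0092 at ppa2. The main value lay above 0 at ppa2.

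Ratios relative to the median gene, an added alternative, gave the count of genes higher in antisense as 0 in swi6Δ, 3 in cid12Δ + nmt1-rdp1+, 4 in wild type + ago1D580A, 5 in arb1Δ, 8 in arb2Δ, 8 in clr4Δ and 21 in chp1Δ. rdp1Δ was at 21, dis3-54,D171N at 39, dcr1Δ at 55 and dcr1Δdis3-54,D171N at 103. Genes lower in antisense numbered 4 in cid12Δ + nmt1-rdp1+, 8 in cid12Δ, 8 in dis3-54,D171N and 63 in dcr1Δdis3-54,D171N against dcr1Δ. Antisense log2 ratios of single genes in wild type + ago1D580A were -1.49 at ppa2, -0.96 at taf12 and -0.25 at gpi12. The main value lay above 0 at ppa2, taf12 and gpi12.

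Totals without the flanks of centromere 3, an added alternative, gave the count of genes higher in antisense as 0 in swi6Δ, 2 in cid12Δ + nmt1-rdp1+, 4 in wild type + ago1D580A, 6 in arb1Δ, 9 in clr4Δ, 11 in arb2Δ and 24 in chp1Δ. rdp1Δ was at 34, dis3-54,D171N at 50 and dcr1Δdis3-54,D171N at 100. Genes lower in antisense numbered 5 in cid12Δ + nmt1-rdp1+, 8 in cid12Δ and 11 in dis3-54,D171N. Antisense log2 ratios of single genes in wild type + ago1D580A were -1.49 at ppa2, -0.97 at taf12 and -0.26 at gpi12. The main value lay above 0 at ppa2, taf12 and gpi12. For the share of other sequence the log2 ratio was 0.49 in dcr1Δ and 2.38 in dis3-54,D171N. Both had been below 0, at -2.61 and -0.66.

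A pseudocount of 20 RPM gave the count of genes higher in antisense as 22 in dcr1Δdis3-54,D171N against dis3-54,D171N, 47 in dis3-54,D171N and 108 in dcr1Δdis3-54,D171N. Genes lower in antisense numbered 6 in dcr1Δdis3-54,D171N against dis3-54,D171N.

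Only reads of 21 to 23 nt gave the ratio of the 2-nt overhang to the mean of the others as 0.981 in swi6Δ, 0.990 in cid12Δ, 0.997 in cid12Δ + nmt1-rdp1+, 1.03 in arb1Δ, 1.09 in wild type and 1.63 in wild type + ago1D580A. Between reads of 20 to 24 nt and these, the ratio crossed 1 in cid12Δ (from 1.03 to 0.990), cid12Δ + nmt1-rdp1+ (from 1.02 to 0.997) and arb2Δ (from 1.001 to 0.992).

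A lower minimum of reads measures more genes by construction, and the shift of the median gene lowers or raises every gene of a comparison alike. Leaving out the flanks of centromere 3, 68.7% of the reads that wild type genes are scaled to, raises every wild type gene value above 0 and lowers the wild type share of other sequence by construction. Whole centromeres take in the tRNA genes of the imr by construction. For all the other values the cause was not tested. With a pseudocount of 1 RPM no count of genes left the range of its main value.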

Other observations

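No test in this part goes beyond the values given, and the places described were chosen after the values were seen. In swi6Δ the plus strand held 63.9% of dg/dh reads left and 36.5% right at centromere 3, against 46.2% and 55.1% in wild type. At centromere 2 it held 64.8% and 36.0%, against 47.4% and 50.6%. At centromere 3, chp1Δ (56.3% and 45.4%) and wild type + ago1D580A (53.8% and 46.5%) leaned the same way, but less. Over all blocks swi6Δ stood at 47.8%.

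Antisense reads of rDNA made 0.393% of the cid12Δ + nmt1-rdp1+ library, 0.249% of swi6Δ and 0.116% of chp1Δ, against 0.0321% of wild type. Reads of 5S rRNA genes made 2.97% of dis3-54,D171N and 0.0235% of wild type. The flanks of centromere 3 held 0.398% of reads in cid12Δ, 0.185% in dis3-54,D171N and 0.0103% in wild type + ago1D580A. Within ago1, which is on the plasmid in every library, reads of the coding span went from 120 in wild type to 13580 in clr4Δ. The chp1 coding span gave 163 reads in cid12Δ, of which 161 lay in its upstream part.

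The last base of sense gene reads differed from the genome in 4.74% of reads in cid12Δ, 6.23% in dis3-54,D171N and 8.20% in clr4Δ, against 26.5% in wild type. Mismatched last bases of dg/dh reads were most often A in wild type + ago1D580A, at 23.1% of dg/dh reads. In each of the 13 libraries the peak file correlated most with the library's own alignments, at r from 0.934 to 0.983 across bases, which are not independent replicates.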
